A study of Arabidopsis thaliana with 6 samples.

How the data were processed

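Total RNA of Arabidopsis thaliana was measured on 6 Affymetrix ATH1 arrays, each a short-oligonucleotide array on which several probes form a probe set for a transcript. The values as deposited are 1 expression level per probe set and array, summarised by the authors from several probes, and were taken as log2 values from their range of about 3 to 14. The scale is not stated in the sources used here, and every fold rests on this reading. Per the submitters' processing notes the tool limma was used, and its version is not given. The background correction, probe summary and normalization are not given in the sources used here, so any compression of low signals by those steps carries over into the differences reported. The array medians were 4.39 to 4.46, a range of 0.0721, and the values were used as deposited with no further scaling. For arrays, their number limits the precision, and the 2 arrays per group are the limit here.

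Samples were grouped by their labels into Col-0 in air, Col-0 treated with ethylene gas and the amiR-ETP1/2 line, with 2 arrays each. The design text calls the replicates biological replicates. The replicate numbers in the array titles link no array of a group to an array of another group beyond the shared number, so the arrays were not paired.

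Of 22753 probe sets, 7 control probe sets were left out of the tests and used as a measure of RNA integrity, and 22746 were tested with no filter on level. A linear model with 1 mean per group was fitted to all 6 arrays in limma 3.58.1 under R 4.3.3, and the spread of each probe set was moderated by the empirical Bayes step with its default prior. The model had 3 residual degrees of freedom per probe set and 4.15 prior degrees of freedom. The 3 contrasts were ethylene minus air, amiR-ETP1/2 minus air and amiR-ETP1/2 minus ethylene. All tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all 22746 probe sets within a contrast. Standard errors (SE) are those of the moderated model with n = 2 arrays per group. A permutation of 2 arrays against 2 cannot reach the threshold, since 33.3% of its outcomes separate the groups by chance, so no permutation test was made on single genes.

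Probe sets were named from the annotation table used here, which gave 1 gene for 13513 probe sets and several genes for 503. The other 8737 probe sets carried no gene name in that table and enter the counts of probe sets but no statement on genes. Of the single-gene probe sets, 13436 were matched to 13286 loci of the TAIR10.1 assembly annotation, which was used only for names, chromosomes and gene order. The genome build behind the array design is not given in the sources used here, and no coordinates are printed.

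Before the data were examined, 24 gene lists with 433 entries were fixed, together with the rule for naming genes and the alternative settings. Of their 426 different loci, 60 were measured by a single-gene probe set. At least 2 members were measured in 17 lists, 1 member in 4 lists and none in 3 lists. A further 17 lists were written after the genes with the largest changes had been seen, and they are called added lists. Each list was represented by 1 probe set per gene, the probe set with the highest mean over the arrays, and was compared with all other probe sets by camera in limma with a preset correlation of 0.01 and again with a correlation estimated from the arrays. The camera p-values were adjusted over 51 tests of fixed lists and 51 tests of added lists. The p-values of list members were also adjusted over the list alone, which is given for fixed lists and some added lists.

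The named genes are, for each contrast, the 10 with the largest rise and the 10 with the largest fall among single-gene probe sets that were called and whose 2 arrays of a group both lay beyond both arrays of the other group. To these were added ETP2, EIN3 and up to 4 members of each list with the smallest p. Any other gene named was chosen after its values were seen.

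For the position of genes, 2786 single-gene nuclear genes with a mean above 6 over the 6 arrays were ordered along the chromosomes, and the median difference between arrays was taken for each chromosome. Its variance was compared with that after circular shifts of the gene order by every possible step. The overlap of the contrasts with air was compared with 100 simulated data sets without any effect of ethylene or genotype, in which the shared air arrays alone link the contrasts. After the overlap had been seen, 100 further data sets were simulated with the observed ethylene differences and no difference in amiR-ETP1/2, and 100 with the called amiR-ETP1/2 differences at probe sets drawn at random.

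The alternatives were quantile normalization, median centring of the arrays, leaving out the 40% of probe sets with the lowest mean, a block for the replicate number, fits of only the 4 arrays of the groups compared, the empirical Bayes step with trend and robust options (statmod 1.5.0), other thresholds, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The procedure was tested on simulated data with 22746 probe sets, of which 100 were changed by 2-fold and 100 by 4-fold. At 2-fold, 95 were called for ethylene against air and 86 for amiR-ETP1/2 against air, and at 4-fold 100 were called in each, beside 19 and 23 false calls.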

Results

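Expression was measured in 3 groups of Arabidopsis thaliana samples labelled as 3 weeks old, with 2 arrays in each group. The groups were the wild type Col-0 in hydrocarbon-free air, Col-0 exposed to the plant hormone ethylene as a gas at 10 ppm, and amiR-ETP1/2. This line carries an artificial microRNA directed against ETP1 and ETP2, which are F-box proteins that the study title links to the breakdown of EIN2, a membrane protein required for ethylene signalling. The exposure is given as 4 h in the sample characteristics and the design text and as 24 h in the array titles. The growth protocol describes seedlings on foil-wrapped plates before a transfer to soil. The labels name no organ, and they give no gas treatment for the amiR-ETP1/2 arrays.

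The ethylene arrays stood far apart from the other 4 arrays. The first principal component held 88.1% of the variance and placed the ethylene arrays at 112 and 113 and the other 4 between -58.4 and -52.7. Across probe sets, which are not independent replicates, Pearson's r between ethylene and air arrays was 0.791 to 0.810, against 0.975 to 0.981 between air and amiR-ETP1/2 arrays. Replicates had an r of 0.987 in air, 0.993 with ethylene and 0.985 in amiR-ETP1/2. The GAPDH control was higher at its 3' than at its 5' end by 0.77 and 1.76 log2 units in the air arrays, 1.02 and 1.76 in the ethylene arrays and 0.52 and 0.66 in the amiR-ETP1/2 arrays.

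The targets of the artificial microRNA were examined first. ETP2 (AT3G18910, chromosome 3) had log2 levels of 4.06 and 4.14 in the air arrays, 4.29 and 4.42 in the ethylene arrays and 4.23 and 4.47 in the amiR-ETP1/2 arrays. The difference of amiR-ETP1/2 from air was 0.25 with an SE of 0.14, and it did not pass the limma test (adjusted p = 0.448). The ETP2 signal lay between percentiles 38.8 and 50.6 of each array, and its air mean was 0.29 log2 units above the 25th percentile. ETP1 and EIN2 had no named probe set in the annotation used here and were not analysed here.

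The comparison of ethylene with air addressed which transcripts differed between treated and untreated Col-0. The named rises started from low log2 levels in air, between 3.44 for AT3G19390 and 4.74 for AT4G38540, beside medians of 4.44 and 4.45 over all probe sets of the air arrays. AT1G72060 rose 159-fold, GAT1_2.1 (AT1G15040), which encodes a protein of the class I glutamine amidotransferase type, rose 113-fold, and MGL (AT1G64660), the methionine gamma-lyase that degrades methionine, rose 93.7-fold from a log2 level of 4.02 to 10.57. AT4G33150, the bifunctional enzyme that starts lysine degradation, rose 83.5-fold, and the granulin-repeat cysteine protease AT3G19390 rose 89.8-fold. The other named rises were AT5G39520 (108-fold), AT4G38540 (82.5-fold), the cold-regulated gene COR27 (77.4-fold), the glucanase-type hydrolase AT4G16260 (72.6-fold) and ARL (AT2G44080), a promoter of organ growth (67.0-fold). The SE of these log2 differences ran from 0.13 for AT3G19390 to 0.25 for AT4G33150, and the adjusted p (limma, Benjamini-Hochberg) was at most 2.62e-06.

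The named falls were in genes of high level in air, and their ethylene levels lay between 3.55 for AT1G13650 and 5.87 for AT4G23670. The signal over background was not measured, so folds above and below that start or end at such low levels are ratios of the deposited values, and neither their exact size nor their order is a measure of transcript number. GSTU20 (AT1G78370), a glutathione transferase of the tau class, fell 157-fold from a log2 level of 11.52 to 4.23, and BCAT4 (AT3G19710), the aminotransferase at the entry of methionine into glucosinolate synthesis, fell 132-fold from 11.34 to 4.29. The other named falls were AT5G05960 (61.7-fold), AT2G43550 (47.5-fold), AT1G75280 (43.4-fold), AT1G65230 (42.2-fold), the lectin-type gene AT5G03350 (41.2-fold), the methionine sulfoxide reductase gene MSRB5 (38.9-fold), AT1G13650 (38.1-fold) and AT4G23670 (35.6-fold). The adjusted p was 1.49e-05 or less, and both ethylene arrays lay below both air arrays for each of these genes.

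Of 22746 probe sets, 8185 (36.0%) were called, 4291 higher and 3894 lower with ethylene. At least 2-fold changes were called for 2533 higher and 2346 lower probe sets, and changes of at least 16-fold for 147 and 136. At the level of named genes, 2308 were higher and 1911 lower. The groups of 2 arrays did not overlap for 66.4% of probe sets, where chance gives 33.3%. In the actin control the ethylene arrays had the largest differences between 3' end and middle and the smallest between 3' and 5' end. Its 3' end exceeded its middle by 0.32 and 0.83 log2 units in the air arrays, 2.17 and 2.02 in the ethylene arrays and 0.89 in each amiR-ETP1/2 array. Its 3' end exceeded its 5' end by 4.04 and 4.68 in air, 3.40 and 3.51 with ethylene and 4.78 and 5.20 in amiR-ETP1/2. The mean actin levels in air and with ethylene were 9.77 and 8.97 at the 3' end and 9.19 and 6.87 in the middle. At the 5' end they were 5.41 and 5.51, so the smaller 3' to 5' difference mainly followed the lower 3' signal. The mean GAPDH levels were 10 and 8.57 at the 3' end and 8.74 and 7.18 at the 5' end.

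Of the genes that respond to ethylene in the list fixed for that purpose, 2 of 22 were measured. RTE1, which acts with the ethylene receptor ETR1, rose 3.71-fold (log2 difference 1.89, SE 0.19, adjusted p = 0.000159). The defensin gene PDF1.2 had a difference of 0.38 (adjusted p = 0.0951). Adjusted over the list alone, both were higher. The list mean was 1.14 and did not pass camera (adjusted p = 0.203, and adjusted p = 0.548 with an estimated correlation). In the list of other ethylene pathway genes, 2 of 3 measured members rose, ARL and the transcription factor EIN3 (AT3G20770). EIN3 rose 4.94-fold from a log2 level of 7.89 to 10.20, ETP2 had a difference of 0.25 (adjusted p = 0.219), and adjusted over the list alone 2 were again higher. This list passed camera with an adjusted p of 0.035, and had an adjusted p = 0.548 with an estimated correlation. AT1G12010, an ACC oxidase of the last step of ethylene synthesis and the 1 measured gene of its list, rose 2.83-fold.

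Nuclear genes of photosynthesis fell together. All 7 measured members of the fixed list fell, with a median log2 difference of -2.23, and all 7 were lower adjusted over the list alone. RCA, the activase of Rubisco, had a log2 difference of -4.12 (SE 0.12), the antenna gene LHCB4.2 fell 10.3-fold, and the photosystem genes PSBY and PSAE-1 fell 5.66-fold and 4.70-fold. The camera adjusted p was 1.2e-05, and the adjusted p = 0.548 with an estimated correlation. In an added list of 15 further genes of photosynthesis, 14 fell, among them NdhL by 4.41, the Calvin cycle gene SBPASE by 3.59 and PORB, of chlorophyll synthesis, by 3.42 on the log2 scale (camera adjusted p = 4.24e-11, and adjusted p = 0.243 with an estimated correlation). The median of 69 genes of the plastid genome was 6.46 and 6.01 in the air arrays and 7.23 and 7.46 in the ethylene arrays.

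Genes of the senescence list and of nutrient recycling were mostly higher. In the fixed senescence list 3 of 4 measured members rose, the transcription factors WRKY22 (4.53-fold), WRKY6 (4.35-fold) and WRKY53 (3.71-fold), while the sugar transporter SAG29 had a difference of 0.08 (adjusted p = 0.89). Adjusted over the list alone the count was also 3, and the list passed camera with an adjusted p of 0.0478 (adjusted p = 0.548 with an estimated correlation). AKINBETA1, a subunit of the SnRK1 energy-sensing kinase, rose 13.9-fold. In the added list of amino acid catabolism 7 of 9 members rose, with a median of 4.48, among them IVD (45.1-fold), MCCA (39.2-fold), MCCB and ETFQO, which act in the breakdown of branched-chain amino acids (camera adjusted p = 4.11e-06, and adjusted p = 0.521 with an estimated correlation). MGL and AT4G33150 belong to this list and were seen before it was written, and without MGL the median was 4.15. All 8 measured ATG genes of autophagy, an added list, rose, led by ATG8B (16.6-fold), ATG8H (16.5-fold) and ATG8E (8.16-fold), with a camera adjusted p of 1.03e-05 and an adjusted p = 0.521 with an estimated correlation. Of 84 cytosolic ribosomal protein genes, also an added list, 61 fell and 1, AT2G19740, rose, with a median of -1.03 (camera adjusted p = 7.31e-16, and adjusted p = 0.521 with an estimated correlation). The added lists were written after the largest changes had been seen, so their p-values are not independent support.

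**Figure D1:**
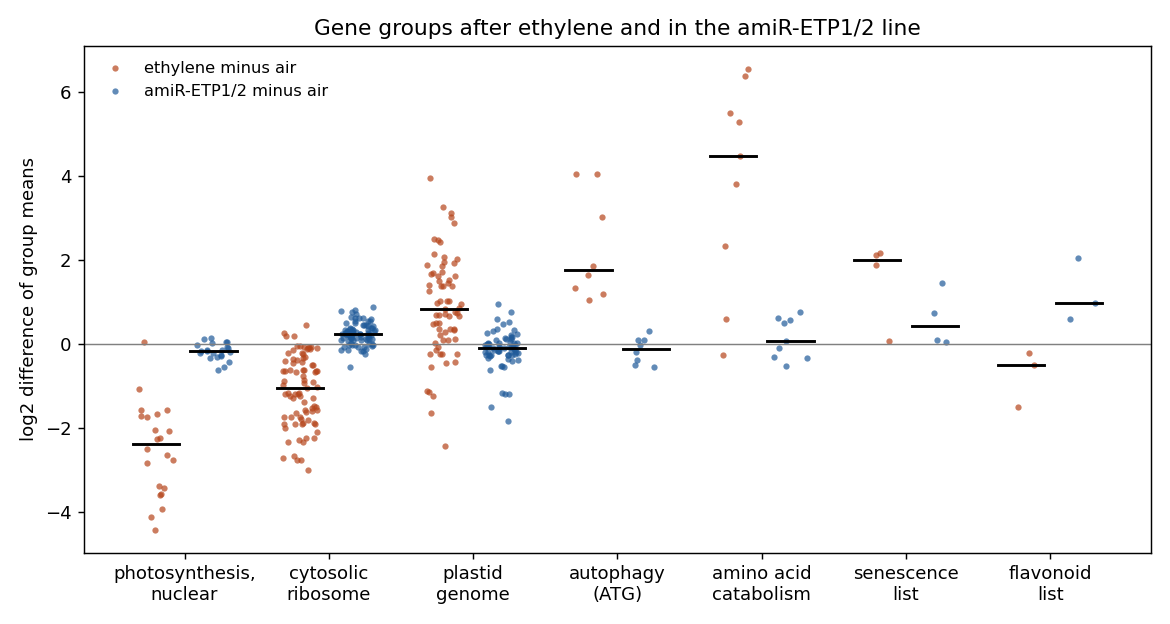
Log2 difference from the air mean for each measured gene (points) of 7 gene groups, for ethylene (orange) and amiR-ETP1/2 (blue), with the group median as a bar and n = 2 arrays per mean. The median of amino acid catabolism genes was 4.48 for ethylene and 0.07 for amiR-ETP1/2, and that of cytosolic ribosomal genes was -1.03 and 0.24.

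The other fixed lists had at most 7 measured members. Both measured glucosinolate genes, BCAT4 and UGT74B1 (2.15-fold), fell (camera adjusted p = 0.0334, and adjusted p = 0.548 with an estimated correlation). Of 7 measured cell wall expansion genes, EXPA8 fell 26.6-fold, EXPA4 12.2-fold and XTH19 1.47-fold, and 4 were not called (camera adjusted p = 0.126). The mitotic kinase genes AUR1 and AUR2 fell 2.05-fold and 1.68-fold, and GI, a clock gene, fell by 1.68 on the log2 scale. Among 7 auxin genes only WES1, an auxin-conjugating enzyme gene, was called and rose 24.1-fold. Of the cytokinin response regulators RR16 rose 13.0-fold and ARR15 fell 1.45-fold. The cold and dehydration genes COR15A and COR15B fell 28.4-fold and 5.66-fold and COR47 rose 2.07-fold. STZ, a zinc-finger gene of rapid stress responses, rose 15.5-fold, and the salicylate genes GRX480 and SAG101 rose 1.64-fold and 1.58-fold. In the hypoxia list AT3G10020 fell 3.34-fold and 2 members were not called, and in the flavonoid list DFR fell 2.81-fold and 2 were not called. Adjusted over the list alone, the counts in these lists were the same. In the jasmonate list 0 of 2 members were called and 1, JMT, was lower adjusted over the list alone. No member was called, or was called adjusted over the list alone, among 3 heat shock genes, the root genes EXPA7 (-0.59, adjusted p = 0.382) and EXPA18 (0.35, adjusted p = 0.133), and the reference genes AT4G34270 (0.44) and AT2G28390 (0.28). Of the lists of this paragraph with at least 2 measured members, only glucosinolate passed camera.

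The comparison of amiR-ETP1/2 with air addressed which transcripts differed in the line with the artificial microRNA. AT5G26270 rose 45.5-fold from a log2 level of 3.96 to 9.47 (log2 difference 5.51, SE 0.20, limma adjusted p = 0.00014). AT4G27280, an EF-hand calcium-binding protein gene, rose 18.7-fold, AT2G37870, of the lipid transfer protein type, rose 13.8-fold and STZ rose 13.6-fold (adjusted p = 0.00993). The other named rises were QQS, an orphan gene tied to starch content (7.79-fold), AT4G33550 (6.63-fold), the expansin-like gene EXLB1 (5.46-fold), the dehydrin gene LTI30 (4.97-fold), AT1G32920 (4.70-fold) and DFR, a reductase of anthocyanin synthesis (4.16-fold, adjusted p = 0.0475). AT5G62360, of the pectin methylesterase inhibitor type, fell 9.51-fold (log2 difference -3.25, SE 0.15, adjusted p = 0.000488).

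Of the 10 largest falls in amiR-ETP1/2, 3 were in glutaredoxin genes of the CC type, AT3G62950 (4.71-fold), AT1G06830 (3.58-fold) and AT3G62930 (2.96-fold). The thionin gene THI2.2 fell 3.51-fold, AT5G40450 3.45-fold, AT3G19550 3.27-fold, AT2G19970 3.07-fold, the endoglucanase-family gene GH9B13 3.02-fold and AT3G46880 2.93-fold. The plastid genes rbcL, of the large Rubisco subunit, and psbA fell by 1.48 (adjusted p = 0.0182) and 1.18 (adjusted p = 0.0434) on the log2 scale. The other 67 of 69 measured plastid genes were not called, and the median difference of this added list was -0.08 (camera adjusted p = 0.186, and adjusted p = 0.826 with an estimated correlation). The plastid genome median was 6.44 and 5.80 in the amiR-ETP1/2 arrays.

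In amiR-ETP1/2 141 of 22746 probe sets (0.62%) were called, 79 higher and 62 lower, and 66 and 50 of them by at least 2-fold. This gave 38 higher and 34 lower named genes, and the smallest called difference was 0.79. At an unadjusted p under 0.05 there were 3446 probe sets. The count was 28 without air array 1, 37 without air array 2, 9 without either ethylene array, 229 without amiR-ETP1/2 array 1 and 252 without array 2. The balance of higher and lower calls moved as well, with 178 and 51 without amiR-ETP1/2 array 1, 119 and 133 without array 2, 23 and 5 without air array 1, 17 and 20 without air array 2, and 8 and 1 from the 4 compared arrays alone. The count was 9 from those 4 arrays, 42 with a replicate block, 259 after quantile normalization, 213 after median centring, 232 with the lowest 40% of probe sets left out and 233 with the trend and robust options.

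The gene groups that moved with ethylene had few calls in amiR-ETP1/2. In the ethylene-induced list RTE1 had a difference of -0.62 (adjusted p = 0.19) and PDF1.2 of -0.03 (adjusted p = 0.951), with 1 lower adjusted over the list alone and a mean of -0.33 (camera adjusted p = 0.367). EIN3 had a difference of 0.11 (adjusted p = 0.84), ARL of 0.46 (adjusted p = 0.186) and AT1G12010 of 0.05 (adjusted p = 0.924). None of 7 photosynthesis genes was called (median -0.14, camera adjusted p = 0.218), none of 15 in the added photosynthesis list (median -0.17, camera adjusted p = 0.0769, 2 lower adjusted over the list alone), and none of 4 senescence genes (adjusted p = 0.0606, 2 higher adjusted over the list alone). The antenna gene LHCB4.3, in none of these lists and chosen after its values were seen, was lower by 1.14 log2 units in amiR-ETP1/2 (adjusted p = 0.0331) and by 3.65 with ethylene. None of 8 ATG genes (median -0.11) and none of 9 amino acid catabolism genes (median 0.07), both added lists, was called. Adjusted over the list alone, 3 amino acid catabolism genes were higher and no ATG gene was called. The flavonoid list had 1 call, DFR, and 3 of 3 members higher adjusted over the list alone, with a median of 0.99 (camera adjusted p = 0.00558, and adjusted p = 0.548 with an estimated correlation). The cold and dehydration list had no call and 2 of 3 higher adjusted over the list alone (camera adjusted p = 0.0235, and adjusted p = 0.548 with an estimated correlation). Of 84 cytosolic ribosomal genes of an added list, 10 were higher adjusted over the list alone and 1, AT4G39200, was called, with a list median of 0.24 (camera adjusted p = 3.02e-11, and adjusted p = 0.521 with an estimated correlation). It lies on chromosome 4, and among the nuclear single-gene probe sets its difference went from 0.87 (SE 0.13, adjusted p = 0.0448) to 0.54 (SE 0.16, adjusted p = 0.129) when the chromosome medians were removed, so the call was lost with a smaller difference and a larger SE. Of the other fixed lists only that of rapid stress responses had a call, STZ. Adjusted over the list alone, 1 member each was lower in the cytokinin, hypoxia, sugar starvation and reference lists, 1 was higher in the ethylene pathway list, and 1 was higher and 1 lower in the auxin list. Over the fixed lists and 3 contrasts, 8 of 51 camera tests passed, and none did with an estimated correlation. With the lowest 40% of probe sets left out 3 passed, the photosynthesis list in both comparisons with the ethylene arrays and the flavonoid list in amiR-ETP1/2.

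The differences of amiR-ETP1/2 from air varied with the chromosome. Over 2786 nuclear genes with a mean level above 6, the median log2 difference was 0.03 on chromosome 1, -0.23 on chromosome 2, 0.11 on chromosome 3, 0.35 on chromosome 4 and -0.25 on chromosome 5. On chromosome 4, 84.5% of 458 genes lay above 0, and on chromosome 5, 21.3% of 626 genes did. Of 2786 circular orders of the genes, the observed order included, 2 gave as large a variance of the chromosome medians (permutation by circular shifts, p = 0.000718). The medians for chromosomes 1 to 5 were 0.01, -0.39, 0.08, 0.24 and -0.32 in amiR-ETP1/2 array 1 and 0.03, -0.04, 0.15, 0.44 and -0.14 in array 2. For ethylene against air they ranged by 0.11 (p = 0.918 by the same permutation), and between the air arrays by 0.03 (p = 0.887). Between the amiR-ETP1/2 arrays they ranged by 0.33 (p = 0.000359 by the same permutation), so the replicates of the line differed by chromosome. Chromosome 4 held 16 of 38 higher nuclear genes and 14.7% of the nuclear single-gene probe sets tested, and chromosome 5 held 15 of 32 lower genes and 22.5% of the probe sets. Single genes went against their chromosome, such as AT5G26270 and DFR, on chromosome 5, which rose.

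**Figure D2:**
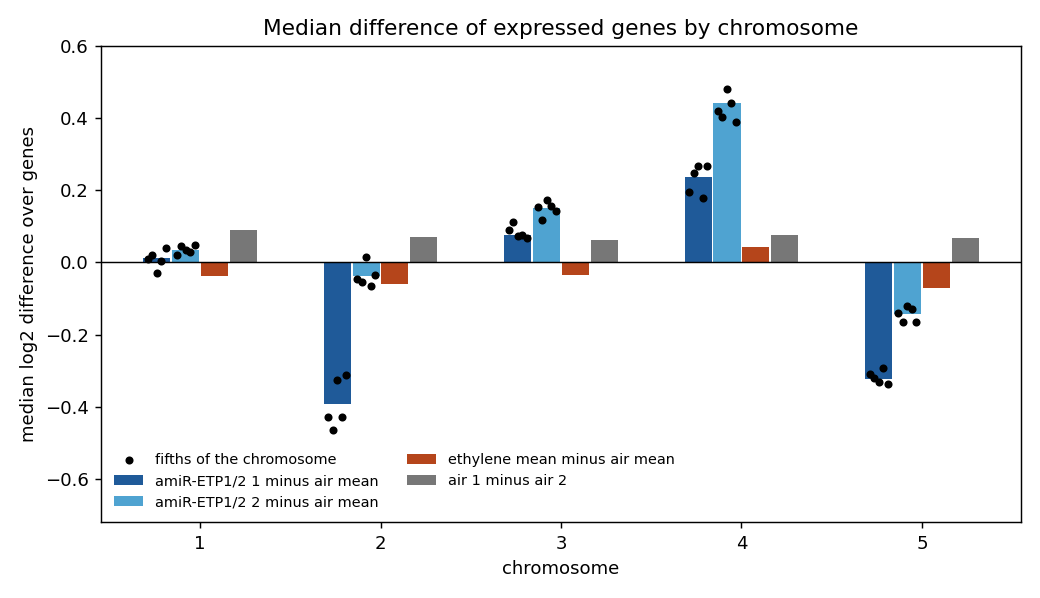
Median log2 difference of expressed nuclear genes on each of the 5 chromosomes for the amiR-ETP1/2 arrays against the air mean (blue bars), the ethylene mean against the air mean (orange) and air array 1 against air array 2 (grey). Black points are the medians of 5 equal parts of each chromosome, and the bars of chromosome 4 stand at 0.24 and 0.44 in the amiR-ETP1/2 arrays.

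The comparison of amiR-ETP1/2 with ethylene addressed how far that line lay from treated wild type. GSTU20 was higher in amiR-ETP1/2 by 7.23 log2 units, BCAT4 by 6.83, AT5G03350 by 6.01, AT3G53980 by 5.93 and COR15A by 5.66. AT4G23670 (5.41), AT2G43550 (5.40), AT1G13650 (5.36), AT5G26270 (5.35) and AT1G75280 (5.28) were the next largest. The largest lower values were in GAT1_2.1 (-6.88), AT1G72060 (-6.85), AT5G39520 (-6.84), AT3G19390 (-6.37), AT1G19530 (-6.33), AT4G38540 (-6.28), COR27 (-6.27), AT3G23550 (-5.98), MGL (-5.97) and AT4G33150 (-5.87). All 7 photosynthesis genes were higher in amiR-ETP1/2 (camera adjusted p = 1.43e-05, and adjusted p = 0.548 with an estimated correlation), as were both glucosinolate genes (adjusted p = 0.0272, and adjusted p = 0.548 with an estimated correlation) and 72 of 84 ribosomal genes of the added list (adjusted p = 3.73e-21, and adjusted p = 0.521 with an estimated correlation). All 8 ATG genes (adjusted p = 1.44e-05) and 8 of 9 amino acid catabolism genes (adjusted p = 3.78e-06) were lower, and each of these added lists had an adjusted p = 0.521 with an estimated correlation. EIN3 was lower by 2.19 and RTE1 by 2.51 log2 units in amiR-ETP1/2, and the mean of the ethylene-induced list was -1.46 (camera adjusted p = 0.195, 2 lower adjusted over the list alone). In all 8731 probe sets were called, 4143 higher and 4588 lower.

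The overlap of the differences from air addressed whether amiR-ETP1/2 and ethylene differed from air in the same transcripts. Of the probe sets called in both, 61 changed in the same direction, 29 higher and 32 lower. Independent lists spread evenly over all probe sets would share 25.5. Both comparisons use the same air arrays. In 100 simulated data sets with the observed ethylene differences, those arrays shared and no difference in amiR-ETP1/2, at most 3 probe sets were called in both in the same direction. Such data sets had at most 4 amiR-ETP1/2 calls (mean 0.3), so few could be shared, and the count of 61 cannot be judged against them. With the 141 called amiR-ETP1/2 differences moved to probe sets drawn at random, the mean was 34.5 (23 to 47) in the same and 30.5 (21 to 47) in opposite directions. These data sets had more ethylene calls (mean 9973) than the 8185 observed. Neither the draws nor the value of 25.5 followed the level of the called probe sets. With the lowest 40% of probe sets left out, 7885 of 13647 were called with ethylene, and 136 of the 141 amiR-ETP1/2 calls remained. The expected and drawn counts are therefore too low for probe sets at the level of these calls. In that setting 111 probe sets were called in both in the same direction and 71 in opposite directions. No expected count was drawn for that setting, so 61 is not read as an excess and an excess is not excluded. Named genes higher in both included AT4G27280 (9.86-fold with ethylene, 18.7-fold in amiR-ETP1/2), STZ (15.5-fold and 13.6-fold), EXLB1 (7.96-fold and 5.46-fold) and AT1G32920 (6.30-fold and 4.70-fold). Those lower in both included AT5G62360 (18.0-fold and 9.51-fold), THI2.2 (19.6-fold and 3.51-fold), GH9B13 (9.28-fold and 3.02-fold) and AT1G06830 (5.05-fold and 3.58-fold). Another 44 probe sets changed in opposite directions, 25 of them higher in amiR-ETP1/2 and lower with ethylene, such as DFR (2.81-fold lower with ethylene) and LTI30 (2.01-fold lower), and 19 the other way, such as AT3G62950 (2.63-fold higher with ethylene) and AT5G40450 (5.59-fold higher). The values expected for independent lists, again spread evenly over all probe sets, were 13.5 and 11.7. AT5G26270 and AT2G37870 were not called with ethylene (log2 differences 0.15 and -0.26).

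Across all probe sets Pearson's r of the log2 differences from air was 0.09, with an SD of the differences of 1.12 for ethylene and 0.32 for amiR-ETP1/2. Their covariance was 0.0325, against a mean of 0.0152 (SD 0.000347) in 100 simulated data sets in which only the shared air arrays link the comparisons. The simulation gave all groups the same spread, while the measured replicates differed more in air than with ethylene. Noise shared between probe sets was not simulated either. The simulated mean and SD may therefore be too low for these air arrays, and 0.0325 is not read as an excess. With a different air array for each comparison the covariance was 0.0224 and -0.0023 and r was 0.05 and -0.01. Without air array 1 the r was 0.18. The count of 61 was 13 without air array 1, 17 without air array 2, 4 without either ethylene array and 137 without amiR-ETP1/2 array 2. Without amiR-ETP1/2 array 1, 82 probe sets changed in the same and 86 in opposite directions. The count of 61 was 123 after quantile normalization, 92 after median centring, 111 with the lowest 40% of probe sets left out, 19 with a replicate block, 5 from the compared arrays alone and 97 with the trend and robust options.

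**Figure D3:**
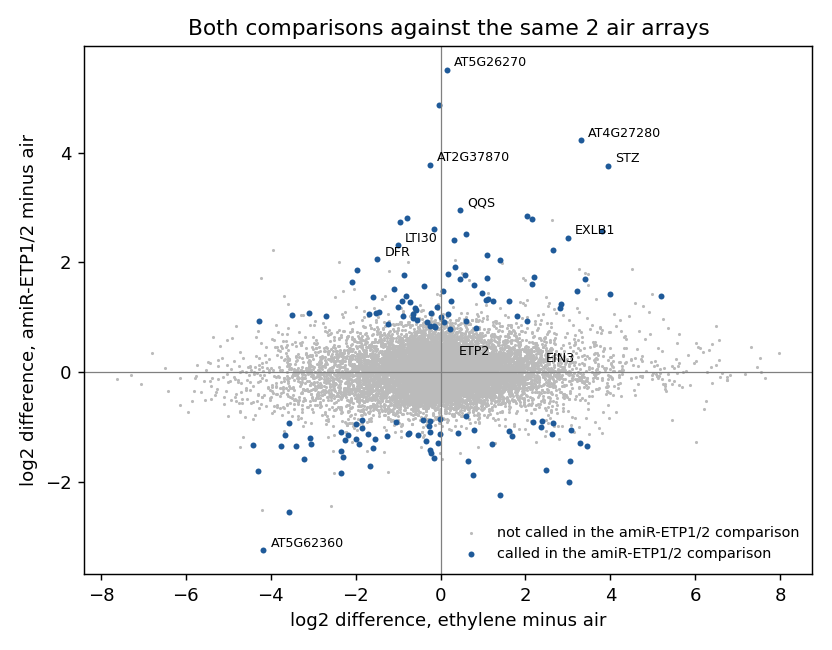
Log2 difference from air of each of 22746 probe sets for ethylene (x axis) and amiR-ETP1/2 (y axis), with the 141 probe sets called in amiR-ETP1/2 in blue and the others in grey. AT5G26270 stands at 0.15 and 5.51, and STZ at 3.95 and 3.76.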

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

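Removing the chromosome medians and leaving out MGL, alone or with AT4G33150, were alternatives chosen after seeing the data, and all others were fixed before. The 8185 calls for ethylene against air and 8731 for amiR-ETP1/2 against ethylene stayed within 1.5 times of these counts under all alternatives but the limit of at least 2-fold, which by its construction gave 4879 and 5147. No called difference of a named gene or list changed sign. The difference of ETP2 in amiR-ETP1/2 stayed between 0.13 and 0.37 and was never called. The ethylene-induced list passed in no contrast and no alternative, with means of 1.06 to 1.21, -0.42 to -0.23 and -1.56 to -1.36, and the setting without the lowest 40% of probe sets gave it no value because fewer than 2 members were left. All 20 named genes of ethylene against air stayed called in every fit and with every array left out. The 20 of amiR-ETP1/2 against air were fewer by 5 with the block, 15 with only the 4 compared arrays or without either ethylene array, 12 without air array 1, 8 without air array 2 and 1 without amiR-ETP1/2 array 1.

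The calls for amiR-ETP1/2 against air (141) and the calls shared with ethylene in the same direction (61) moved most. They were 259 and 123 with quantile normalization, 213 and 92 with median centring, 232 and 111 with the lowest 40% left out, 9 and 5 with only the compared arrays, and 233 and 97 with the trend and robust options. An adjusted p under 0.10 gave 451 calls, at least 2-fold 116, and an unadjusted p under 0.01 in both contrasts 476 shared ones. With arrays left out, the calls ranged from 9 (without either ethylene array) to 252 (without amiR-ETP1/2 array 2), with 28 and 37 without air arrays 1 and 2 and 229 without amiR-ETP1/2 array 1. With single arrays left out, higher calls outnumbered lower ones (79 and 62 with all arrays) except without amiR-ETP1/2 array 2 (119 and 133) and without air array 2 (17 and 20). The shared calls ranged from 4 (without either ethylene array) to 137 (without amiR-ETP1/2 array 2), with 13 and 17 without air arrays 1 and 2 and 82 without amiR-ETP1/2 array 1. Calls in opposite directions (44) outnumbered the shared ones only without amiR-ETP1/2 array 1, with 86. They were 363 with the unadjusted p and 0 to 76 in the other settings. The correlation of the differences from air ranged from 0.0694 (without amiR-ETP1/2 array 2) to 0.185 (without air array 1). A group left with 1 array gives no spread of its own and was assumed to vary like the others. Without either ethylene array, the fit of amiR-ETP1/2 against air is therefore that of only the compared arrays. These settings are the same check for that contrast, and its count of calls depends on the spread lent by the ethylene arrays. The cause of the other movements was not tested. Of the other list tests 8 passed, and 3 did with the lowest 40% left out, with a range of 3 to 10 over the alternatives. The pseudocount alternative was not run, as the values were taken as log2.

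A block for the replicate number gave 42 calls and 19 shared ones, at the cost of 1 degree of freedom. The pairing rests on the shared number alone, and the deviations of replicate 1 from its group mean had correlations across genes of -0.137 between air and ethylene, -0.169 between air and amiR-ETP1/2 and 0.0686 between ethylene and amiR-ETP1/2.

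For each array, the chromosome medians of the differences from the air mean were taken over the 2786 genes. They were subtracted from all 13367 nuclear single-gene probe sets. After that step 199 were called in amiR-ETP1/2 against air, 87 higher and 112 lower. Without it 85 were called (46 and 39), and 69 were called in both. Probe sets of low level were moved by the same amount, and whether the step itself made calls was not tested. The median of the cytosolic ribosomal list was 0.25 after the step and 0.24 before it. The signal over background was not measured, and 38.8% or more of the probe sets of each array lay below ETP2.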

Other observations

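Of the tests in this part, those of neighbouring genes, chromosome dosage, root tissue, carbon starvation, RNA quality and the ETP2 signal were chosen only after the result was seen, as were the glutaredoxin and the added gene lists, and those of scaling were not.

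Genes of the plastid genome were mostly higher in signal with ethylene while nuclear photosynthesis genes were lower. Whether this signal follows plastid transcript levels was not tested, and in air psbA had a log2 level of 7.11, beside 13.26 for RCA. Of 69 plastid genes 38 rose, led by petL (3.96), ndhA (3.26) and ndhE (3.12 log2 units), and 3 fell, atpB (-2.42), petA (-1.64) and cemA (-1.14), while rbcL was not called (-0.23, limma adjusted p = 0.364). The list median was 0.84 (camera adjusted p = 4.01e-07, and adjusted p = 0.624 with an estimated correlation). Ethylene arrays also had 4 of 7 calmodulin-like genes higher, with CML41 up 31.6-fold (camera adjusted p = 0.0148, and adjusted p = 0.521 with an estimated correlation). Of 11 tau glutathione transferase genes GSTU20, GSTU18 (11.3-fold) and GSTU27 (3.99-fold) fell and GSTU16 rose 3.65-fold. Of 14 sugar transporter genes of the SWEET family 3 rose, among them SWEET2 (9.16-fold), 2 fell, among them SWEET17 (11.8-fold), and 9 were not called (camera adjusted p = 0.612). Among 18 expansin genes EXPA8, EXPA4 and EXPB3 (9.66-fold) fell and EXLB1 (7.96-fold) and EXLA1 (1.75-fold) rose, and 4 of 15 endoglucanase genes of the GH9 family fell, GH9B13 by 3.21 log2 units.

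In amiR-ETP1/2, 17 of 21 CC-type glutaredoxin genes were measured, and 4 fell and 0 rose. They were AT3G62930, AT3G62950, AT1G06830 and AT5G18600 (-0.81, adjusted p = 0.0475). The other 13 had a median of -0.27 with a range of -0.98 to 0.55, and 8 lay below 0. The list was written after some of its members had been seen, so no test of it is given, and with ethylene 7 of its members rose and 3 fell. Among the nuclear single-gene probe sets, removal of the chromosome medians took AT5G18600 from -0.81 (SE 0.12, adjusted p = 0.044) to -0.57 (SE 0.16, adjusted p = 0.104), and its call was lost.

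The amiR-ETP1/2 arrays had chromosome-wide shifts, up on chromosome 4 and down on chromosome 5, which differed in size between the arrays (chromosome 2 lay lower by 0.34 log2 units in array 1 than in array 2). Neighbouring genes that change together are argued against, since 0.0718% of circular orders of the genes, the observed order included, gave as large a spread of medians. Quantile normalization left the distance of chromosomes 4 and 5 at 0.586 against 0.595. It treats all chromosomes of an array alike and could hardly change this distance, so it does not decide on scaling between arrays. The shifts may reflect unequal chromosome dosage in the plants, as all 20 medians, over 5 parts of chromosome 4 and 5 parts of chromosome 5 in each array, had the sign of their chromosome. Over all 5 chromosomes 48 of 50 medians did, and on chromosome 2 of array 2, where the median was -0.04, they ran from -0.07 to 0.01. This is a hypothesis found and tested on the same data, with chromosomes 4 and 5 picked for their shifts, and neither DNA nor an effect of the artificial microRNA itself was tested.

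The ethylene arrays lay far from all others, with 36.0% of probe sets called. After quantile normalization 8463 were called, so unequal distributions of the deposited values do not account for the count. The array medians already lay within 0.0721 log2 units, so this step could change little. Scaling in the earlier processing, which is not given, was not tested. Root tissue in the ethylene samples was predicted to lower the median of plastid genes. That median was higher in every pair of an ethylene and an air array, by at least 0.632 log2 units. Whether the plastid signal of these arrays follows the plastid content of the tissue was not tested. In air psbA had a log2 level of 7.11, beside 13.26 for RCA. The plastid genes therefore cannot decide on root tissue, which stays open. A response of the carbon starvation type could account for part of the pattern. Amino acid catabolism genes other than MGL had a median rise of 4.15, ATG genes rose and ribosomal genes fell. Without AT4G33150 as well the median was 3.81. These lists were written after the largest changes had been seen, so this is a hypothesis without independent support. In the fixed sugar starvation list 1 of 6 members was measured, AKINBETA1, which rose. RNA quality stays open as well. Actin 3' minus middle was higher in both ethylene arrays than in all others, by at least 1.12 log2 units. Actin 3' minus 5' was lower in both, with a mean 3' level of 8.97 against 9.77 in air and a 5' level near that of air. GAPDH 3' minus 5' overlapped with the air arrays. Whether ethylene itself, the 4 h or 24 h of exposure, or darkness or a closed container during treatment led to the pattern stays open, as the design has no array that separates them.

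ETP2 was not lower in amiR-ETP1/2 than in air. A signal too low to show a fall is a possible explanation, since the air mean of ETP2 lay 0.295 log2 units above the 25th percentile of all probe sets. The lowest values of the air arrays were 3.07 and 3.11. As signal over background was not measured, how much room a loss of transcript had to appear is not known. An artificial microRNA that acts on translation rather than on transcript level was not tested.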
